A study of Drosophila melanogaster with 9 samples.

How the data were processed

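Total RNA from pools of 50 larval midguts, 1 pool per array and 3 biological replicates per group according to the labels, was labelled with biotin and hybridised to Affymetrix fly arrays. The deposited table holds 1 signal intensity per probe set and array, on a linear scale. Per the labels, the authors used the Affymetrix software GCOS, whose version, algorithm and scaling target are not given in the sources used here. Signals ran from 0.0520 to 12490, and the highest and lowest 2% trimmed array means differed 1.90-fold, so a common scaling was not visible. Detection calls were not analysed here. All 9 columns were mapped to samples by their labels, and the labels name no date or batch. The identifiers of the control samples lie apart from those of both treatments, so a batch shared with group could be neither checked nor excluded.

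The 44 control probe sets were left out of the comparisons. An offset of 1.72, the 20th percentile of the signals, was added before taking log2. Because the trimmed means differed by over 10%, the log2 values were quantile normalised, which sets equal distributions on all arrays and removes any difference in total RNA signal between groups. A probe set was tested where at least 3 of the 9 arrays lay above the 40th percentile, a signal of 5.18 (log2 2.79). That left 9675 of 13966 probe sets. Annotation gave 1 gene for 12443 probe sets, several for 327 and none for 1196, and 12394 of those with 1 gene matched the reference table of symbols. Where a gene had several tested probe sets (627 genes), the brightest stood for it in the gene lists. With this normalisation the median log2 change of all tested probe sets was 0.03, 0.01 and 0.01 (WGA against control, starvation against control, WGA against starvation). It was 0.47, 0.12 and 0.35 with the deposited scaling and 0.54, 0.59 and -0.05 with spike-in scaling. Median centring over all probe sets gave 0.08, -0.03 and 0.11, while the alternative that was run centred the tested probe sets again. Below, such a median is called the shift of all tested probe sets, without subtraction of the main value. All changes are given relative to the quantile-normalised distribution.

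Group means were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with the contrasts WGA minus control, starvation minus control and WGA minus starvation. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over 9675 probe sets. Errors beside log2 changes are the standard errors of this fit. Replicate numbers were not used as pairs, since residual correlations were -0.038 to 0.096 between arrays of the same number and -0.130 to 0.059 between arrays of different numbers. Still, 6 of the 9 arrays correlated best with an array of their own number. A weak pairing is therefore not excluded, and a replicate block was run as an alternative. Named genes are the 10 largest rises and the 10 largest falls per contrast past the threshold, with 1 gene per probe set and no overlap between the arrays of the groups. To these were added up to 4 of the largest changes of each list and the 5 clearest opposite changes.

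Each of 40 fixed gene lists, 32 of functions and 8 of markers of other cell types, was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a contrast. The number of changed members is given over all probe sets and adjusted over the list alone. After the first results had been computed, 6 wrong matches were removed from the lists by gene identity, 5 of them synonyms shared with another gene and 1 a gene listed by mistake. Listed genes without a probe set of their own were not analysed here. The overlap of the comparisons was set against 100 simulations of unchanged groups sharing the controls. The lists, tests, filters, naming rule and alternatives were chosen before the data were examined, except scaling on the 9 spike-in probe sets, 10 further lists and the tests of brightness, of ribosomal proteins, of the share of enterocytes and of the actin probe sets, which were chosen after seeing the data.

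Alternatives covered the deposited scaling, cyclic loess, median centring, other offsets and filters, a variance prior without a trend, array weights, only the groups compared, a replicate block, a minimum absolute log2 change of 1, the median probe set per gene, other set tests and each array left out in turn. The fit was tested on simulated data of 9675 probe sets. Changes of each size were set in 100 of them for either treatment against control, and in 200 for WGA against starvation. Of 2-fold changes the fit recovered 18%, 19% and 28.5% in WGA against control, starvation against control and WGA against starvation. Of 4-fold changes it recovered 60%, 58% and 64.5%. The false share of calls was 1.27%, 6.10% and 2.62%. In the real data 21.7%, 15.2% and 11.5% of probe sets were called, a larger share than was simulated as changed, so these rates need not hold there. Genome positions were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.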

Results

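Midgut transcripts of white-eyed w1118 Drosophila melanogaster larvae of the third instar were measured on 9 Affymetrix arrays in 3 groups of 3. Control larvae were labelled as 120 h old, and their titles name a normal state and 12 h. The other groups were labelled 108 h (108 to 110 h for WGA replicate 1). They spent 12 h on a diet with 1% wheat germ agglutinin (WGA), a lectin of wheat that binds N-acetylglucosamine and chitin, or without food. The 108 h were read as the age at the start of these 12 h, so a difference in age from the controls is not excluded. Each array held RNA from 1 pool of 50 midguts, so the error terms describe the spread between pools. The deposited signals summed to 909030 to 1457200 per array, and the number of arrays limits the precision. Of 14010 probe sets, 9675 were bright enough to be tested, covering 7905 genes. Pearson r across tested probe sets, which are not independent replicates, was 0.907 to 0.950 within groups and 0.843 to 0.905 between groups. The first principal component held 33.7% of the variance and the next 19.6%. The 3 prime to 5 prime signal ratio of the eIF-4a control probe sets, a measure of RNA integrity, was 3.60 to 5.71 on the control arrays, 2.75 to 3.52 after WGA and 2.83 to 3.56 after starvation. The GAPDH ratio ordered the groups otherwise, at 1.97 to 2.92, 2.22 to 2.41 and 2.92 to 3.35, and the actin ratio overlapped, at 1.44 to 2.36, 1.17 to 1.49 and 1.44 to 1.51. The labels give no date or batch, so a batch shared with a group could be neither checked nor excluded. Values that follow gene names are log2 changes ± SE of the fit, with n = 3 arrays per group.

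The WGA diet was set against control to ask which transcripts respond to the lectin. Lip3, a triglyceride lipase, was at a log2 signal of 3.97 ± 1.02 in control and 9.87 ± 0.58 after WGA (mean ± SD, n = 3), a log2 change of 5.89 ± 0.40 (SE). The chitinase gene Cht4 5.85 ± 0.27, the glutathione S-transferase genes GstD2 4.87 ± 0.25 and GstD3 3.82 ± 0.21, the mucin gene Muc26B 3.88 ± 0.38 and the amylase-related gene Amyrel 3.70 ± 0.17 rose with it. The largest falls were AANATL6 -6.85 ± 0.61, an N-acetyltransferase-like gene, the lysozyme gene LysS -5.79 ± 0.12, CG5892 -5.57 ± 0.29, CG12115 -5.57 ± 0.25 and the trypsin gene thetaTry -5.29 ± 0.26. In all, 1125 probe sets rose and 975 fell among 9675 tested, 745 and 681 of them at least 2-fold. The 3 arrays of each group did not overlap for 38.3% of tested probe sets, against 10% by chance.

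Other large rises were CG7248 5.05 ± 0.19, CG18404 3.88 ± 0.17, CG34166 3.70 ± 0.58 and the antifungal peptide gene Drs 4.88 ± 0.57. Other large falls were the lipase-family genes CG6277 -5.27 ± 0.21, CG6295 -5.09 ± 0.30 and CG6283 -5.05 ± 0.20, with CG17191 -4.97 ± 0.23 and CG3819 -4.83 ± 0.22. By the naming rule, each of these 20 genes had no overlap between the 3 arrays of the groups. Drs in control, at 2.47 ± 1.04, and CG12115 after WGA, at 1.67 ± 0.12, lay below the filter level of 2.79, so the size of their changes is uncertain. The same holds for GstD5 and dome in control, at 2.24 ± 0.55 and 2.06 ± 0.31, and after WGA for Cyp6t1 at 2.10 ± 0.32, Cyp304a1 at 2.42 ± 0.73, Mal-A8 at 2.32 ± 0.72, Ugt35B1 at 2.24 ± 0.61 and Ugt37B1 at 2.20 ± 0.55, all named among the lists.

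Among trypsins and chymotrypsin-like digestive proteases, 17 of 30 fell and 1 rose (18 and 1 adjusted over the list alone), camera adjusted p = 2.79e-08, adjusted p = 0.021 with an estimated correlation. The falls included Jon25Bi -2.65 ± 0.34, Jon99Fi -2.50 ± 0.20 and Jon25Bii -2.49 ± 0.18 beside thetaTry. Of genes for carbohydrate digestion, 10 of 21 fell and 3 rose (10 and 3 adjusted over the list alone), camera adjusted p = 0.0244, adjusted p = 0.331 with an estimated correlation. For the carbohydrate digestion genes the median was -0.35, and 0.132 with the deposited scaling and 0.134 with spike-in scaling, where the median of all tested probe sets shifted by 0.47 and 0.54 and the list had adjusted p = 0.000976 and 0.00128 (median over the alternatives -1.477 to 0.134). This call was lost, with adjusted p = 0.0827 with no filter. That median was -1.477 with a filter at the 60th percentile and -0.028 without a filter. The maltase gene Mal-A8 -3.52 ± 0.61 and the mannosidase genes LManII -2.97 ± 0.24 and LManVI -2.91 ± 0.18 fell, while Amyrel rose. Of genes for lipid digestion and sterol handling, 6 of 20 rose and 4 fell (7 and 5 adjusted over the list alone), camera adjusted p = 0.719. Lip3 rose, and CG6277, CG6295 and CG6283 fell. Among cathepsins and lysozymes, 6 of 14 fell and 3 rose (7 and 5 adjusted over the list alone), camera adjusted p = 0.0142, adjusted p = 0.46 with an estimated correlation. For the cathepsins and lysozymes the adjusted p missed the threshold at 0.0827 without control replicate 3, and also at 0.0524 with a replicate block (range over the alternatives 9.23e-05 to 0.46). Their median was -0.62, but 0.074 with a filter at the 60th percentile. LysS fell with LysC -4.38 ± 0.18, LysE -4.28 ± 0.17 and LysD -3.25 ± 0.18, whose near-identical sequences allow shared probes.

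Of the peritrophic matrix and chitin-binding proteins, which line the midgut lumen, 7 of 19 rose and 0 fell (10 and 0 adjusted over the list alone), camera adjusted p = 0.0131, adjusted p = 0.331 with an estimated correlation. The threshold was missed at adjusted p = 0.0574 with median centring. Besides Muc26B, obst-J 2.64 ± 0.52, obst-G 2.31 ± 0.47 and Peritrophin-15b 2.19 ± 0.46 rose. Among enzymes of chitin synthesis and remodelling, 4 of 23 rose and 0 fell (3 and 0 adjusted over the list alone), camera adjusted p = 0.0545. For the chitin enzymes the adjusted p passed the threshold at 0.0494 without control replicate 3, 0.0468 without WGA replicate 1 and 0.0343 without WGA replicate 2 (range over the alternatives 0.000568 to 0.255). The risers included Cht4, Cht9 3.13 ± 0.17 and the deacetylase gene Cda9 2.95 ± 0.60.

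Detoxification genes went both ways. Of the cytochrome P450 genes, 19 of 62 fell and 11 rose (19 and 12 adjusted over the list alone), camera adjusted p = 0.0455, adjusted p = 0.525 with an estimated correlation. The median of the P450 genes was -0.29, and 0.276 with the deposited scaling and 0.319 with spike-in scaling, where the median of all tested probe sets shifted by 0.47 and 0.54 and the list had adjusted p = 0.0272 and 0.0188 (median over the alternatives -0.383 to 0.319). For the P450 genes the adjusted p missed the threshold at 0.0964 without control replicate 2, 0.174 without control replicate 3, 0.073 without WGA replicate 1 and 0.0895 without WGA replicate 2, and also at 0.0515 with cyclic loess, 0.0687 with no filter, 0.0957 with a filter at the 60th percentile and 0.0571 with a replicate block (range over the alternatives 0.0127 to 0.525). Cyp4d14 -3.59 ± 0.38, Cyp4d1 -3.31 ± 0.17, Cyp6t1 -3.12 ± 0.38 and Cyp4d2 -2.91 ± 0.23 fell. Among glutathione S-transferases, 13 of 31 rose and 8 fell (14 and 12 adjusted over the list alone), camera adjusted p = 0.0877. GstD9 3.51 ± 0.24 and GstD5 3.05 ± 0.38 rose beside GstD2 and GstD3. Of the UDP-glycosyltransferases, 7 of 26 fell and 0 rose (7 and 1 adjusted over the list alone), with 4 falls without control replicate 2, camera adjusted p = 0.0903. For the UDP-glycosyltransferases the adjusted p passed the threshold at 0.0245 without control replicate 1 and 0.048 without WGA replicate 3 (range over the alternatives 0.00305 to 0.321). Ugt37B1 -4.26 ± 0.31, Ugt35B1 -2.47 ± 0.42 and Ugt302C1 -2.01 ± 0.17 fell. Among antioxidant genes and Nrf2 targets, 8 of 16 fell and 1 rose (8 and 1 adjusted over the list alone), camera adjusted p = 0.0119, adjusted p = 0.103 with an estimated correlation. For the antioxidant genes the median was -0.58, and 0.027 with the deposited scaling and 0.095 with spike-in scaling, where the median of all tested probe sets shifted by 0.47 and 0.54 and the list had adjusted p = 0.0183 and 0.0143 (median over the alternatives -0.84 to 0.095). Malic enzyme Men -1.80 ± 0.23, the mitochondrial proteins Prx3 -1.65 ± 0.26 and Sod2 -1.43 ± 0.22, and Gclm -1.59 ± 0.17 fell. For metal binding and transport, 2 of 17 fell and 1 rose (2 and 1 adjusted over the list alone), camera adjusted p = 0.151. The copper importer gene Ctr1B -2.56 ± 0.25 fell.

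Of the oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, 44 of 53 fell and 0 rose (44 and 0 adjusted over the list alone), camera adjusted p = 2.3e-25, adjusted p = 0.103 with an estimated correlation. Their median was -1.23, with ND-15 -2.02 ± 0.20, ATPsynE -1.93 ± 0.14, ATPsynO -1.88 ± 0.17 and ATPsynbeta -1.85 ± 0.20 among the falls. The eIF-4a 3 prime to 5 prime ratio was also higher on the control arrays, at 3.60 to 5.71, than after WGA, at 2.75 to 3.52, while the GAPDH and actin ratios overlapped. Among fatty acid oxidation genes, 10 of 13 fell and 0 rose (10 and 0 adjusted over the list alone), camera adjusted p = 6.47e-07, adjusted p = 0.0246 with an estimated correlation. Acox3 -2.19 ± 0.15, colt -1.65 ± 0.21, yip2 -1.63 ± 0.16 and scu -1.55 ± 0.19 fell. For glycolysis and gluconeogenesis, 10 of 19 fell and 0 rose (11 and 1 adjusted over the list alone), camera adjusted p = 1.43e-05, adjusted p = 0.103 with an estimated correlation. The falls included phosphoenolpyruvate carboxykinase Pepck1 -2.70 ± 0.17, pyruvate carboxylase PCB -2.07 ± 0.22, Gpdh1 -1.67 ± 0.21 and Pgk -1.24 ± 0.16. Of the vacuolar ATPase subunits, 9 of 20 fell and 0 rose (9 and 1 adjusted over the list alone), camera adjusted p = 0.000426, adjusted p = 0.0989 with an estimated correlation. Vha100-4 -1.25 ± 0.18, Vha44 -1.13 ± 0.18 and Vha14-1 -1.04 ± 0.13 fell. Among genes of lipid synthesis and lipoproteins, 11 of 22 fell and 3 rose (12 and 3 adjusted over the list alone), camera adjusted p = 0.0212, adjusted p = 0.218 with an estimated correlation. For lipid synthesis and lipoproteins the adjusted p missed the threshold at 0.0609 with a filter at the 60th percentile. The lipid droplet gene Lsd-1 -2.88 ± 0.51 and Agpat3 -2.59 ± 0.18 fell, and the lipoprotein receptor gene LpR2 1.91 ± 0.23 rose. Of sugar and amino acid transporters, 6 of 19 fell and 2 rose (6 and 2 adjusted over the list alone), with 3 falls without WGA replicate 1, camera adjusted p = 0.0437, adjusted p = 0.167 with an estimated correlation. The median of the transporters was -0.34, and 0.077 with the deposited scaling and 0.1 with spike-in scaling, where the median of all tested probe sets shifted by 0.47 and 0.54 and the list had adjusted p = 0.0714 and 0.0668 (median over the alternatives -0.545 to 0.1). For the transporters the adjusted p missed the threshold at 0.0827 without control replicate 3 and 0.0563 without WGA replicate 1, and also at 0.0714 with the deposited scaling, 0.0587 with median centring, 0.0901 with a filter at the 60th percentile, 0.0575 with a replicate block and 0.0668 with spike-in scaling (range over the alternatives 0.000201 to 0.167). sbm -3.06 ± 0.40, MFS3 -2.24 ± 0.27 and gb -1.71 ± 0.26 fell. For FOXO, TOR and fasting genes, 4 of 19 rose and 3 fell (6 and 3 adjusted over the list alone), camera adjusted p = 0.941. The insulin-binding protein gene ImpL2 2.83 ± 0.27 rose and Lip4 -2.01 ± 0.20 fell.

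Of the proteasome subunits, 24 of 30 rose and 0 fell (24 and 0 adjusted over the list alone), camera adjusted p = 2.71e-09, adjusted p = 0.277 with an estimated correlation. Prosalpha2 1.43 ± 0.18, Prosbeta2 1.29 ± 0.19, Prosbeta4 1.27 ± 0.19 and Prosbeta5 1.24 ± 0.20 rose. Among unfolded protein response genes and secretory chaperones, 7 of 17 rose and 0 fell (7 and 0 adjusted over the list alone), camera adjusted p = 0.00489, adjusted p = 0.0989 with an estimated correlation. Sil1 2.68 ± 0.30, a co-chaperone of the endoplasmic reticulum, CaBP1 1.04 ± 0.18 and ERp60 1.01 ± 0.15 rose. Of the autophagy genes, 6 of 18 rose and 0 fell (7 and 0 adjusted over the list alone), with 2 rises without WGA replicate 2, camera adjusted p = 0.00321, adjusted p = 0.331 with an estimated correlation. Atg8a 1.66 ± 0.18 and Atg3 1.18 ± 0.23, of the conjugation system, rose. Among heat shock proteins, 3 of 13 rose and 0 fell (3 and 0 adjusted over the list alone), camera adjusted p = 0.218. stv 1.58 ± 0.34, Droj2 0.90 ± 0.14 and Hsc70-4 0.88 ± 0.14 rose. Of the ribosome biogenesis genes, 6 of 28 rose and 0 fell (7 and 0 adjusted over the list alone), with 1 rises without control replicate 3, camera adjusted p = 0.0116, adjusted p = 0.448 with an estimated correlation. bys 1.72 ± 0.30 rose. For cytosolic ribosomal proteins, 5 of 30 rose and 0 fell (5 and 0 adjusted over the list alone), camera adjusted p = 0.106. RpL27 0.64 ± 0.14 and RpS7 0.49 ± 0.12 rose.

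Of the cytoskeleton and brush border genes, 12 of 23 rose and 1 fell (14 and 1 adjusted over the list alone), camera adjusted p = 0.000194, adjusted p = 0.0989 with an estimated correlation. cpa 1.91 ± 0.22, which caps actin filaments, the spectrin gene kst 1.23 ± 0.24, Myo28B1 1.13 ± 0.28 and Klc 1.11 ± 0.20 rose. Among septate and adherens junction genes, 4 of 16 rose and 0 fell (5 and 0 adjusted over the list alone), camera adjusted p = 0.0119, adjusted p = 0.103 with an estimated correlation. The smooth septate junction genes mesh 1.54 ± 0.17, Tsp2A 1.51 ± 0.13 and Ssk 1.00 ± 0.14 rose with l(2)gl 1.18 ± 0.30. In the list of peptidoglycan recognition and the IMD pathway, 6 of 12 rose and 1 fell (6 and 1 adjusted over the list alone), camera adjusted p = 0.00938, adjusted p = 0.252 with an estimated correlation. The NF-kB factor gene Rel 2.21 ± 0.23, PGRP-LA 1.87 ± 0.29, pirk 1.18 ± 0.26 and key 1.01 ± 0.19 rose. Of JAK-STAT, EGFR and JNK genes of gut renewal, 5 of 11 rose and 0 fell (6 and 0 adjusted over the list alone), camera adjusted p = 0.00321, adjusted p = 0.0989 with an estimated correlation. The cytokine receptor gene dome 3.21 ± 0.31 and the EGFR ligand gene Krn 1.12 ± 0.26 rose. Among antimicrobial peptides, 1 of 5 rose and 1 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.82, where the median was -0.51, the mean 0.19 and the direction of the test down. Drs rose and AttD -2.33 ± 0.53 fell. Of the apoptosis genes, 3 of 9 rose and 0 fell (3 and 0 adjusted over the list alone), camera adjusted p = 0.0848. For the apoptosis genes the adjusted p passed the threshold at 0.0361 without control replicate 1 (range over the alternatives 0.00109 to 0.279). The caspase gene Dcp-1 2.32 ± 0.20 rose.

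Among enteroendocrine markers, 3 of 12 fell and 1 rose (3 and 1 adjusted over the list alone), camera adjusted p = 0.18. AstC -0.91 ± 0.20 fell. Of visceral muscle markers, 1 of 15 rose and 1 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.887. Act87E 0.78 ± 0.14 rose and Argk1 -0.94 ± 0.15 fell. For Malpighian tubule markers, 3 of 9 fell and 0 rose (6 and 2 adjusted over the list alone), camera adjusted p = 0.0455, adjusted p = 0.255 with an estimated correlation. For the tubule markers the adjusted p missed the threshold at 0.0786 without control replicate 2, 0.075 without control replicate 3 and 0.073 without WGA replicate 1, and also at 0.0557 with median centring, 0.0603 with no filter and 0.0681 with the median probe set of a gene (range over the alternatives 0.00366 to 0.255). Smvt -2.54 ± 0.27 fell. In the fat body list, 1 of 5 fell and 0 rose (1 and 0 adjusted over the list alone), camera adjusted p = 0.7, where the median was 0.19, the mean -0.39 and the direction of the test down. That gene was regucalcin -2.10 ± 0.27. In adult midgut progenitor markers 0 of 6 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.787. In the trachea list 0 of 3 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.307. Of the hemocyte markers, 0 of 10 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.879. Of the salivary gland markers, 0 of 5 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.82. The ecdysone response list gave 0 of 12 that rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.481. For DNA replication and cell cycle, 0 of 24 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.719.

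In all, 21 of 40 fixed lists passed camera in this comparison, and trypsins and fatty acid oxidation also passed with an estimated correlation. With fry 29 passed. These included lists that missed with camera, such as glutathione S-transferases (fry adjusted p = 0.00127), UDP-glycosyltransferases (0.00305), lipid digestion (0.00366, down) and apoptosis (0.00109). Member counts of 5 or fewer often moved by more than 1.5 times when 1 array was left out, and the split of 53.6% higher among changed probe sets was 82.2% with the deposited scaling and 84.4% with spike-in scaling.

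**Figure D1:**
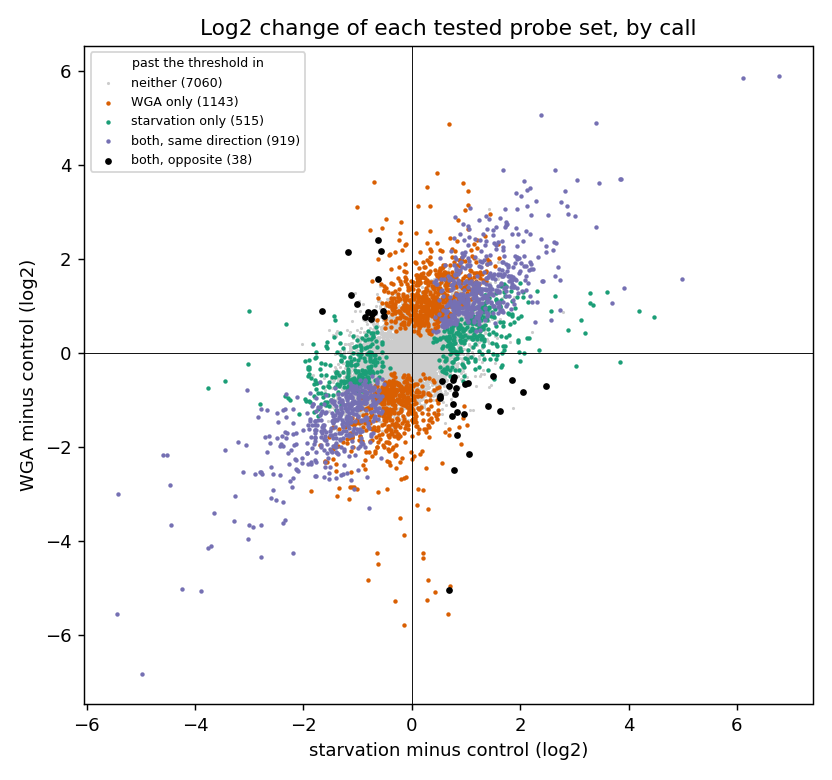
Each point is 1 of 9675 tested probe sets, with its log2 change after starvation (x axis) and after WGA (y axis) against the same 3 control arrays, coloured by the comparisons in which it passed the threshold. Of these, 1143 passed after WGA only, 515 after starvation only, 919 in both in the same direction and 38 in opposite directions.

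Starvation was set against control to ask which transcripts respond to lack of food. Lip3 went from 3.97 ± 1.02 to 10.76 ± 0.16 log2 signal (mean ± SD, n = 3), a change of 6.78 ± 0.40 (SE). Cht4 6.12 ± 0.27, CG12951 4.99 ± 0.28, the lipase-family genes CG6271 4.46 ± 0.30 and CG31089 3.84 ± 0.51, and Amyrel 3.84 ± 0.17 rose. The transcription factor gene sug, which responds to dietary sugar, fell by 5.42 ± 0.33 on the log2 scale, with CG5892 -5.43 ± 0.29, AANATL6 -4.98 ± 0.61, CG3348 -4.59 ± 0.20 and the alkaline phosphatase gene Alp4 -3.75 ± 0.38. Among 9675 probe sets, 786 rose and 686 fell, 506 and 449 of them at least 2-fold. Groups did not overlap for 29.4% of tested probe sets, against 10% by chance.

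BomS6 3.91 ± 0.28, CG34166 3.86 ± 0.58, fok 3.69 ± 0.32 and Sil1 3.40 ± 0.30 also rose. CG5157 -4.51 ± 0.26, Phyhd1 -4.46 ± 0.33, the pantetheine hydrolase-like gene vanin-like -4.44 ± 0.54, CG3706 -3.76 ± 0.29 and CG15155 -3.70 ± 0.42 fell. After starvation sug (1.73 ± 0.23), CG5157 (2.34 ± 0.15), Phyhd1 (2.41 ± 0.71), pippin (2.28 ± 0.20) and CG15155 (2.66 ± 0.18) lay below the filter level of 2.79 in log2 signal (mean ± SD), so their changes are uncertain in size.

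Of genes for lipid digestion and sterol handling, 7 of 20 rose and 0 fell (7 and 1 adjusted over the list alone), with 4 rises without control replicate 2, camera adjusted p = 0.00548, adjusted p = 0.198 with an estimated correlation. CG8093 2.51 ± 0.29 rose with Lip3, CG6271 and CG31089. Among carbohydrate digestion genes, 7 of 21 rose and 2 fell (10 and 3 adjusted over the list alone), camera adjusted p = 0.0434, adjusted p = 0.608 with an estimated correlation. For the carbohydrate digestion genes the adjusted p missed the threshold at 0.0664 without control replicate 1, 0.0667 without control replicate 3 and 0.175 without starvation replicate 3, and also at 0.125 with the deposited scaling, 0.134 with median centring, 0.105 with a filter at the 60th percentile, 0.0727 with a replicate block and 0.135 with spike-in scaling (range over the alternatives 0.013 to 0.608). Amyrel, Mal-A4 1.94 ± 0.18 and Mal-A3 1.56 ± 0.25 rose and LManV -1.40 ± 0.21 fell. Of the trypsin-like proteases, 5 of 30 fell and 3 rose (6 and 4 adjusted over the list alone), camera adjusted p = 0.782. alphaTry 2.16 ± 0.20 rose, and Jon99Ci -1.21 ± 0.20, Jon44E -1.07 ± 0.22 and Jon99Fi -0.99 ± 0.20 fell. In the cathepsin and lysozyme list, 3 of 14 rose and 0 fell (6 and 0 adjusted over the list alone), camera adjusted p = 0.00691, adjusted p = 0.672 with an estimated correlation. This call was lost, with adjusted p = 0.122 with the deposited scaling, 0.224 with median centring and 0.0779 with fry. The risers were the proteases CtsF 2.12 ± 0.33, Bace 2.11 ± 0.27 and CtsL1 1.38 ± 0.21. Among peritrophic matrix proteins, 7 of 19 rose and 0 fell (7 and 0 adjusted over the list alone), with 4 rises without control replicate 2, camera adjusted p = 0.00548, adjusted p = 0.465 with an estimated correlation. The threshold was missed at adjusted p = 0.0696 with fry. Muc26B 2.64 ± 0.38 and Muc11A 2.40 ± 0.37 rose. Of the chitin enzymes, 3 of 23 rose and 0 fell (3 and 0 adjusted over the list alone), camera adjusted p = 0.00402, adjusted p = 0.159 with an estimated correlation. Cht9 2.86 ± 0.17 rose beside Cht4.

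Of the oxidative phosphorylation genes, 43 of 53 fell and 0 rose (45 and 0 adjusted over the list alone), camera adjusted p = 2.29e-30, adjusted p = 0.159 with an estimated correlation. Their median was -1.19, and ATPsyndelta -1.89 ± 0.24, SdhC -1.79 ± 0.19, ATPsynO -1.78 ± 0.17 and COX5A -1.78 ± 0.14 fell. The eIF-4a 3 prime to 5 prime ratio was 2.83 to 3.56 after starvation and 3.60 to 5.71 in control, while the GAPDH ratio was 2.92 to 3.35 after starvation and 1.97 to 2.92 in control. For fatty acid oxidation, 6 of 13 fell and 0 rose (8 and 2 adjusted over the list alone), with 3 falls without control replicate 1, camera adjusted p = 0.00258, adjusted p = 0.159 with an estimated correlation. Acox3 -1.15 ± 0.15, yip2 -1.01 ± 0.16 and Arc42 -0.76 ± 0.16 fell. In glycolysis and gluconeogenesis, 7 of 19 fell and 2 rose (8 and 2 adjusted over the list alone), camera adjusted p = 0.00402, adjusted p = 0.315 with an estimated correlation. Hexokinase Hex-A 1.82 ± 0.22 rose, and Gpdh1 -1.67 ± 0.21, PCB -1.61 ± 0.22 and Pepck1 -1.52 ± 0.17 fell. Of vacuolar ATPase subunits, 9 of 20 fell and 2 rose (9 and 2 adjusted over the list alone), camera adjusted p = 0.000123, adjusted p = 0.159 with an estimated correlation. Vha14-1 -1.43 ± 0.13, Vha16-1 -1.14 ± 0.12 and Vha13 -1.08 ± 0.12 fell. In lipid synthesis, 7 of 22 fell and 4 rose (9 and 5 adjusted over the list alone), camera adjusted p = 0.402, where the median was 0.02, the mean -0.27 and the direction of the test down. Fatty acid synthase FASN1 -3.06 ± 0.51, Agpat3 -2.76 ± 0.18 and AcCoAS -2.19 ± 0.22 fell and the acyltransferase gene mino 2.06 ± 0.26 rose. Among transporters, 5 of 19 fell and 2 rose (5 and 3 adjusted over the list alone), camera adjusted p = 0.428. sbm -3.26 ± 0.40, pippin -2.67 ± 0.31 and MFS3 -1.55 ± 0.27 fell and acs 1.76 ± 0.26 rose. Of the FOXO, TOR and fasting genes, 4 of 19 rose and 3 fell (5 and 4 adjusted over the list alone), camera adjusted p = 0.949. REPTOR-BP 1.60 ± 0.16 and Atg8a 1.60 ± 0.18 rose, and sug and Pepck1 fell.

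For cytochrome P450 genes, 11 of 62 rose and 11 fell (14 and 13 adjusted over the list alone), with 6 falls without control replicate 2, camera adjusted p = 0.743. Cyp6g1 2.48 ± 0.20 rose, and Cyp4d14 -3.29 ± 0.38, Cyp6a8 -3.20 ± 0.43 and Cyp6a2 -2.56 ± 0.23 fell. Of the glutathione S-transferases, 10 of 31 fell and 7 rose (12 and 9 adjusted over the list alone), camera adjusted p = 0.421. GstT4 2.73 ± 0.21 and GstD9 2.19 ± 0.24 rose and GstE8 -2.84 ± 0.24 and GstE7 -2.48 ± 0.40 fell. The UDP-glycosyltransferase list held 26 genes, of which 5 fell and 3 rose (5 and 3 adjusted over the list alone), camera adjusted p = 0.743, where the median was 0.07, the mean -0.15 and the direction of the test down. Ugt37B1 -2.19 ± 0.31 and Ugt49B1 -1.83 ± 0.20 fell. In the antioxidant list, 6 of 16 fell and 1 rose (7 and 2 adjusted over the list alone), camera adjusted p = 0.00548, adjusted p = 0.159 with an estimated correlation. For the antioxidant genes the median was -0.48, and 0.004 with spike-in scaling, where the median of all tested probe sets shifted by 0.59 and the list had adjusted p = 0.00406 (median over the alternatives -0.619 to 0.004). Trx2 -2.38 ± 0.22, Men -1.86 ± 0.23, Prx3 -1.76 ± 0.26 and Sod2 -1.28 ± 0.22 fell. Of the metal list, 2 of 17 fell and 1 rose (2 and 1 adjusted over the list alone), camera adjusted p = 0.964. Ctr1B -1.19 ± 0.25 fell.

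Among unfolded protein response genes and secretory chaperones, 6 of 17 rose and 0 fell (6 and 0 adjusted over the list alone), camera adjusted p = 0.0199, adjusted p = 0.159 with an estimated correlation. For unfolded protein response and secretory chaperones the adjusted p missed the threshold at 0.0957 with the deposited scaling, 0.221 with median centring and 0.0663 with a filter at the 60th percentile. CaBP1 1.89 ± 0.18, the BiP gene Hsc70-3 1.24 ± 0.19 and Gp93 1.15 ± 0.17 rose beside Sil1. In heat shock proteins, 4 of 13 rose and 1 fell (6 and 3 adjusted over the list alone), camera adjusted p = 0.175. For the heat shock proteins the adjusted p passed the threshold at 0.0307 without starvation replicate 3 (range over the alternatives 0.0307 to 0.672). DnaJ-1 2.12 ± 0.31 rose and l(2)efl -0.87 ± 0.18 fell. Of proteasome subunits, 7 of 30 rose and 0 fell (8 and 0 adjusted over the list alone), with 1 rises without control replicate 1 and 12 rises without starvation replicate 1, camera adjusted p = 0.00402, adjusted p = 0.672 with an estimated correlation. For the proteasome subunits the adjusted p missed the threshold at 0.15 without starvation replicate 3, and also at 0.192 with the deposited scaling, 0.224 with median centring and 0.211 with fry (range over the alternatives 1.67e-06 to 0.672). Rpn13 1.02 ± 0.21 rose. In the autophagy list, 3 of 18 rose and 0 fell (3 and 0 adjusted over the list alone), camera adjusted p = 0.00548, adjusted p = 0.608 with an estimated correlation. For the autophagy genes the adjusted p missed the threshold at 0.0587 without starvation replicate 3, and also at 0.0696 with fry (range over the alternatives 0.00122 to 0.608). Atg8a rose. For ribosome biogenesis, 5 of 28 rose and 0 fell (5 and 0 adjusted over the list alone), camera adjusted p = 0.0448, adjusted p = 0.672 with an estimated correlation. For the ribosome biogenesis genes the adjusted p missed the threshold at 0.0765 without control replicate 2, 0.278 without control replicate 3 and 0.359 without starvation replicate 1, and also at 0.062 with cyclic loess, 0.0663 with a filter at the 60th percentile, 0.0538 with only the 2 groups compared in the fit and 0.183 with fry (range over the alternatives 0.0115 to 0.672). bys 1.32 ± 0.30 rose. Among ribosomal proteins, 4 of 30 rose and 0 fell (4 and 0 adjusted over the list alone), camera adjusted p = 0.398. RpL28 1.14 ± 0.23 and RpL40 0.52 ± 0.12 rose. Of IMD pathway and peptidoglycan recognition genes, 6 of 12 rose and 0 fell (6 and 0 adjusted over the list alone), camera adjusted p = 0.00258, adjusted p = 0.198 with an estimated correlation. Rel 1.55 ± 0.23 and PGRP-LE 1.12 ± 0.19 rose. Of the renewal signalling genes, 3 of 11 rose and 0 fell (3 and 0 adjusted over the list alone), camera adjusted p = 0.0154, adjusted p = 0.159 with an estimated correlation. For the renewal signalling genes the adjusted p missed the threshold at 0.0504 without starvation replicate 3 (range over the alternatives 0.00305 to 0.159). dome 2.76 ± 0.31 and kay 1.39 ± 0.32 rose. In antimicrobial peptides, 1 of 5 rose and 0 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.905, where the median was -0.36, the mean 0.10 and the direction of the test down. Drs 3.39 ± 0.57 rose. Among cytoskeleton genes, 3 of 23 rose and 2 fell (3 and 2 adjusted over the list alone), camera adjusted p = 0.897, where the median was 0.04, the mean 0.05 and the direction of the test down. alphaTub84D -1.70 ± 0.20 fell. Of junction genes, 1 of 16 rose and 0 fell (1 and 0 adjusted over the list alone), camera adjusted p = 0.132. mesh 0.85 ± 0.17 rose. For apoptosis, 1 of 9 rose and 0 fell (2 and 0 adjusted over the list alone), camera adjusted p = 0.421.

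In visceral muscle markers, 2 of 15 fell and 0 rose (2 and 0 adjusted over the list alone), camera adjusted p = 0.397, where the median was 0.02, the mean -0.15 and the direction of the test down. Argk1 -2.12 ± 0.15 fell. Of hemocyte markers, 2 of 10 rose and 0 fell (2 and 0 adjusted over the list alone), camera adjusted p = 0.628, where the median was -0.13, the mean 0.16 and the direction of the test up. NimC2 1.80 ± 0.41 and crq 0.98 ± 0.19 rose. Among tubule markers, 2 of 9 fell and 0 rose (3 and 1 adjusted over the list alone), camera adjusted p = 0.435. Smvt -2.78 ± 0.27 and Oatp58Dc -2.08 ± 0.48 fell. Of fat body markers, 1 of 5 rose and 1 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.905. regucalcin -1.77 ± 0.27 fell. In the enteroendocrine list, 1 of 12 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.628. For adult midgut progenitors, 0 of 6 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.586. For trachea, 0 of 3 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.883. For salivary gland, 0 of 5 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.883. For the ecdysone response, 0 of 12 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.338. In DNA replication and cell cycle, 0 of 24 rose and 0 fell (0 and 0 adjusted over the list alone), camera adjusted p = 0.883.

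Under camera, 16 of 40 lists passed, and 0 did so with an estimated correlation (9 at an unadjusted p under 0.05, and 14 with fry after adjustment). The 786 higher probe sets became 507 without starvation replicate 2, and the share of 53.4% higher was 41.7% with median centring and 87.3% with spike-in scaling.

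**Figure D2:**
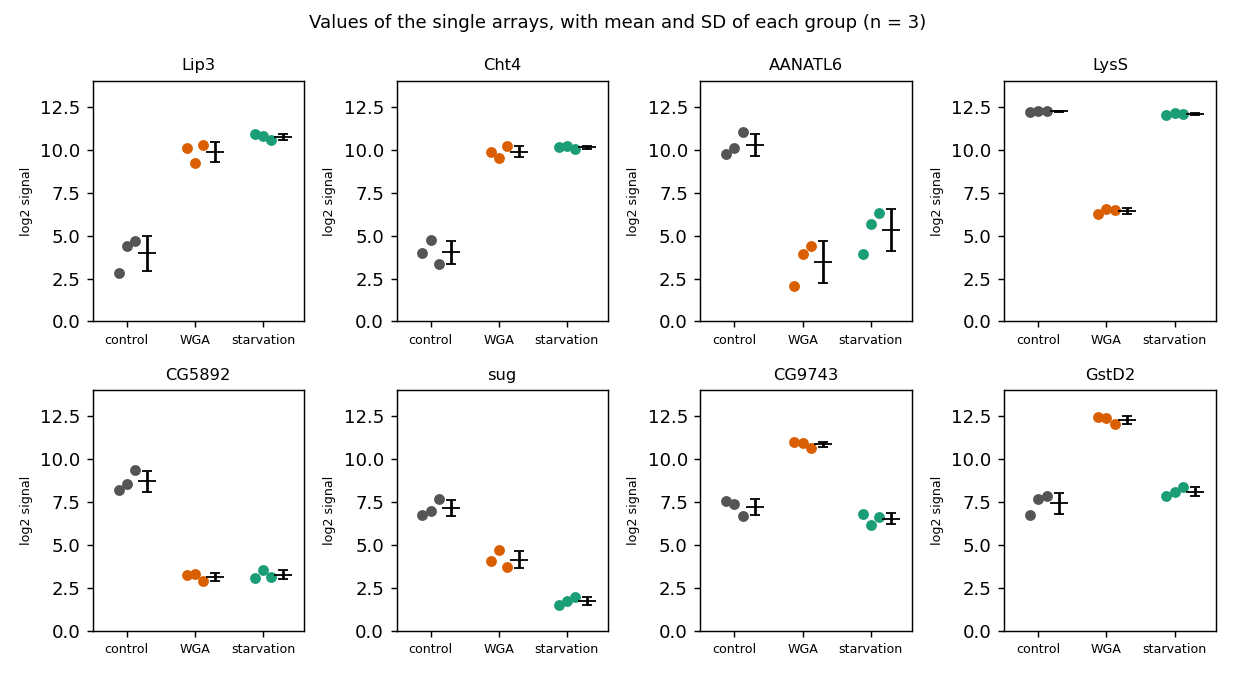
Log2 signal (y axis) of 8 genes on each array (coloured points) in the control, WGA and starvation groups, with the mean ± SD of each group in black (n = 3). Lip3 had means of 3.97 ± 1.02, 9.87 ± 0.58 and 10.76 ± 0.16, and LysS had means of 12.23 ± 0.05, 6.44 ± 0.16 and 12.09 ± 0.05.

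WGA was set against starvation to test directly where the responses differ. LysS, a lysozyme gene, was at a log2 signal of 6.44 ± 0.16 after WGA and 12.09 ± 0.05 after starvation (mean ± SD, n = 3), a difference of -5.65 ± 0.12 (SE). CG12115 -6.23 ± 0.25, the lipase-family genes CG6283 -5.73 ± 0.20, CG6277 -5.55 ± 0.21 and CG6295 -5.51 ± 0.30, and thetaTry -4.98 ± 0.26 were lower after WGA. CG9743 4.32 ± 0.22, GstD2 4.19 ± 0.25, GstD3 3.36 ± 0.21 and the insulin-binding protein gene ImpL2 3.31 ± 0.27 were higher. In total 575 probe sets were higher after WGA and 539 lower, 361 and 341 of them at least 2-fold. Arrays of the groups did not overlap for 30.0% of tested probe sets, against 10% by chance.

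CG8834 4.11 ± 0.43, CG10182 3.88 ± 0.38, the glucuronyltransferase gene GlcAT-S 3.37 ± 0.26, CG33116 3.32 ± 0.24, CG5550 3.25 ± 0.20 and CG44014 3.02 ± 0.16 were also higher. CG17191 -5.68 ± 0.23, CG3819 -5.14 ± 0.22, LysC -4.59 ± 0.18 and LysE -4.48 ± 0.17 were lower. CG12115 after WGA was below the filter level, and LysC and LysE have near-identical copies in the genome.

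Among trypsin-like proteases, 14 of 30 were lower and 0 higher (15 and 0 adjusted over the list alone), camera adjusted p = 3.3e-11, adjusted p = 0.00793 with an estimated correlation. Jon25Bii -3.28 ± 0.18, Jon74E -2.60 ± 0.27 and Jon25Bi -2.55 ± 0.34 were lower with thetaTry. In carbohydrate digestion, 14 of 21 were lower and 0 higher (16 and 0 adjusted over the list alone), camera adjusted p = 1.1e-10, adjusted p = 0.0707 with an estimated correlation. Mal-A8 -3.30 ± 0.61, LManIII -2.90 ± 0.31, Mal-A6 -2.55 ± 0.40 and LManII -2.35 ± 0.24 were lower. For lipid digestion, 6 of 20 were lower and 2 higher (6 and 2 adjusted over the list alone), camera adjusted p = 0.00124, adjusted p = 0.18 with an estimated correlation. For the lipid digestion genes the median was -0.27, and 0.036 with the deposited scaling, where the median of all tested probe sets shifted by 0.35 and the list had adjusted p = 3.88e-08 (median over the alternatives -0.557 to 0.036). CG31089 -4.05 ± 0.51 was lower. In cathepsins and lysozymes, 6 of 14 were lower and 0 higher (6 and 0 adjusted over the list alone), camera adjusted p = 1.27e-09, adjusted p = 0.213 with an estimated correlation. LysD -3.34 ± 0.18 was lower. Of peritrophic matrix proteins, 1 of 19 were lower and 0 higher (1 and 0 adjusted over the list alone), camera adjusted p = 0.828. Muc18B -0.84 ± 0.16 was lower. In the chitin enzymes, 1 of 23 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.534.

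Of the glutathione S-transferases, 16 of 31 were higher and 3 lower (16 and 5 adjusted over the list alone), camera adjusted p = 2.41e-05, adjusted p = 0.127 with an estimated correlation. GstE9 2.54 ± 0.25 and GstE6 2.12 ± 0.23 were higher. In the P450 list, 16 of 62 were lower and 4 higher (18 and 6 adjusted over the list alone), camera adjusted p = 0.000475, adjusted p = 0.44 with an estimated correlation. The median of the P450 genes was -0.37, and 0.083 with the deposited scaling, where the median of all tested probe sets shifted by 0.35 and the list had adjusted p = 0.00336 (median over the alternatives -0.451 to 0.083). Cyp4p1 2.73 ± 0.18 was higher, and Cyp6g1 -3.19 ± 0.20, Cyp304a1 -2.71 ± 0.43 and Cyp4d1 -2.51 ± 0.17 were lower. Among UDP-glycosyltransferases, 5 of 26 were lower and 2 higher (9 and 3 adjusted over the list alone), camera adjusted p = 0.135. Ugt37B1 -2.08 ± 0.31 and Ugt303A1 -1.53 ± 0.23 were lower. Of antioxidant genes, 3 of 16 were lower and 2 higher (3 and 3 adjusted over the list alone), camera adjusted p = 0.94, where the median was 0.06, the mean -0.01 and the direction of the test down. Trx2 1.16 ± 0.22 and Gtpx 0.78 ± 0.13 were higher, and Gclm -1.29 ± 0.17 and Gclc -0.86 ± 0.18 lower. In metal binding and transport, 3 of 17 were lower and 0 higher (5 and 1 adjusted over the list alone), camera adjusted p = 0.135. For the metal-binding list the adjusted p passed the threshold at 0.0247 without starvation replicate 1 (range over the alternatives 0.0205 to 0.347). MtnC -2.47 ± 0.51, Ctr1B -1.37 ± 0.25 and MtnB -1.32 ± 0.28 were lower.

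In fatty acid oxidation, 8 of 13 were lower and 1 higher (9 and 1 adjusted over the list alone), with 4 lower without starvation replicate 2, camera adjusted p = 4.06e-05, adjusted p = 0.058 with an estimated correlation. This call was lost, with adjusted p = 0.0856 with the deposited scaling. colt -1.26 ± 0.21, Acox3 -1.04 ± 0.15 and CRAT -0.85 ± 0.19 were lower. Of glycolysis and gluconeogenesis genes, 6 of 19 were lower and 0 higher (8 and 0 adjusted over the list alone), camera adjusted p = 0.0135, adjusted p = 0.44 with an estimated correlation. For the glycolysis genes the median was -0.36, and 0.079 with the deposited scaling, where the median of all tested probe sets shifted by 0.35 and the list had adjusted p = 0.479 (median over the alternatives -0.466 to 0.079). For the glycolysis genes the adjusted p missed the threshold at 0.0583 without starvation replicate 2 and 0.07 without WGA replicate 3, and also at 0.479 with the deposited scaling, 0.169 with median centring and 0.218 with spike-in scaling (range over the alternatives 0.00063 to 0.479). Hex-A -1.20 ± 0.22 and Pepck1 -1.18 ± 0.17 were lower. Among oxidative phosphorylation genes, 1 of 53 were lower and 0 higher (0 and 0 adjusted over the list alone), camera adjusted p = 0.437. For the respiratory chain list the adjusted p passed the threshold at 0.0436 without starvation replicate 3 (range over the alternatives 0.0436 to 0.991). For the vacuolar ATPase, 2 of 20 were lower and 0 higher (2 and 6 adjusted over the list alone), camera adjusted p = 0.603. Vha100-4 -1.20 ± 0.18 was lower. Of lipid synthesis genes, 4 of 22 were lower and 2 higher (6 and 2 adjusted over the list alone), camera adjusted p = 0.313. mino -2.89 ± 0.26 was lower and LpR1 1.93 ± 0.36 higher. In transporters, 2 of 19 were lower and 1 higher (2 and 1 adjusted over the list alone), camera adjusted p = 0.289. pippin 1.46 ± 0.31 was higher and slif -0.84 ± 0.16 lower. Among FOXO, TOR and fasting genes, 4 of 19 were lower and 2 higher (5 and 3 adjusted over the list alone), camera adjusted p = 0.617, where the median was -0.20, the mean 0.06 and the direction of the test down. ImpL2 and sug 2.42 ± 0.33 were higher, and Lip4 -0.92 ± 0.20 lower.

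In cytoskeleton and brush border genes, 11 of 23 were higher and 0 lower (12 and 0 adjusted over the list alone), camera adjusted p = 4.13e-06, adjusted p = 0.058 with an estimated correlation. cpa 1.83 ± 0.22, cofilin tsr 1.30 ± 0.16, Arpc1 1.27 ± 0.14 and Fim 1.17 ± 0.16 were higher. For the proteasome, 12 of 30 were higher and 0 lower (16 and 0 adjusted over the list alone), with 1 higher without WGA replicate 2, camera adjusted p = 1.75e-06, adjusted p = 0.513 with an estimated correlation. The threshold was missed at adjusted p = 0.0889 with fry. Prosbeta4 1.02 ± 0.19 was higher. Among junction genes, 3 of 16 were higher and 0 lower (4 and 0 adjusted over the list alone), camera adjusted p = 0.18. Tsp2A 1.13 ± 0.13 and Ssk 1.06 ± 0.14 were higher. For apoptosis genes, 1 of 9 were higher and 0 lower (1 and 0 adjusted over the list alone), camera adjusted p = 0.467. That gene was Dcp-1 2.43 ± 0.20. Of the unfolded protein response genes, 3 of 17 were higher and 2 lower (3 and 4 adjusted over the list alone), camera adjusted p = 0.851. PEK 1.34 ± 0.25 and ERp60 0.93 ± 0.15 were higher and CaBP1 -0.85 ± 0.18 lower. Of heat shock proteins, 2 of 13 were lower and 1 higher (3 and 1 adjusted over the list alone), camera adjusted p = 0.94, where the median was 0.32, the mean -0.42 and the direction of the test up. DnaJ-1 -1.81 ± 0.31 was lower. In the IMD list, 2 of 12 were lower and 1 higher (3 and 5 adjusted over the list alone), camera adjusted p = 0.745. bsk 0.97 ± 0.21 was higher, and PGRP-SC2 -1.34 ± 0.14 and Tab2 -0.82 ± 0.17 lower. In renewal signalling, 2 of 11 were higher and 0 lower (2 and 0 adjusted over the list alone), camera adjusted p = 0.416. Krn 1.18 ± 0.26 was higher. In autophagy, 2 of 18 were higher and 1 lower (2 and 1 adjusted over the list alone), camera adjusted p = 0.617. Of antimicrobial peptides, 0 of 5 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.95, where the median was -0.15, the mean 0.09 and the direction of the test up. Of ribosomal proteins, 1 of 30 were higher and 1 lower (1 and 1 adjusted over the list alone), camera adjusted p = 0.617. Of ribosome biogenesis genes, 0 of 28 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.467.

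Of the visceral muscle markers, 2 of 15 were higher and 0 lower (2 and 0 adjusted over the list alone), camera adjusted p = 0.241. Act87E 1.30 ± 0.14 and Argk1 1.18 ± 0.15 were higher. In hemocyte markers, 2 of 10 were lower and 0 higher (2 and 0 adjusted over the list alone), camera adjusted p = 0.492. crq -1.08 ± 0.19 was lower. Of the tubule markers, 1 of 9 were lower and 0 higher (1 and 0 adjusted over the list alone), camera adjusted p = 0.389. NKCC -1.17 ± 0.26 was lower. Of the enteroendocrine markers, 0 of 12 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.437. In progenitor markers, 0 of 6 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.814. In trachea markers, 0 of 3 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.467. In fat body markers, 0 of 5 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.617. In salivary gland markers, 0 of 5 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.706. Of ecdysone response genes, 1 of 12 were lower and 0 higher (1 and 0 adjusted over the list alone), camera adjusted p = 0.828. Of DNA replication genes, 2 of 24 were higher and 0 lower (0 and 0 adjusted over the list alone), camera adjusted p = 0.92, where the median was -0.10, the mean 0.05 and the direction of the test up.

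Of 40 lists, 10 passed camera, and the trypsin-like proteases also passed with an estimated correlation. With fry 14 passed. The higher count of 575 was 363 without WGA replicate 2 and the lower count of 539 was 358 without starvation replicate 2, while the share of 51.6% higher was 84.9% with the deposited scaling and 62.3% with median centring.

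**Figure D3:**
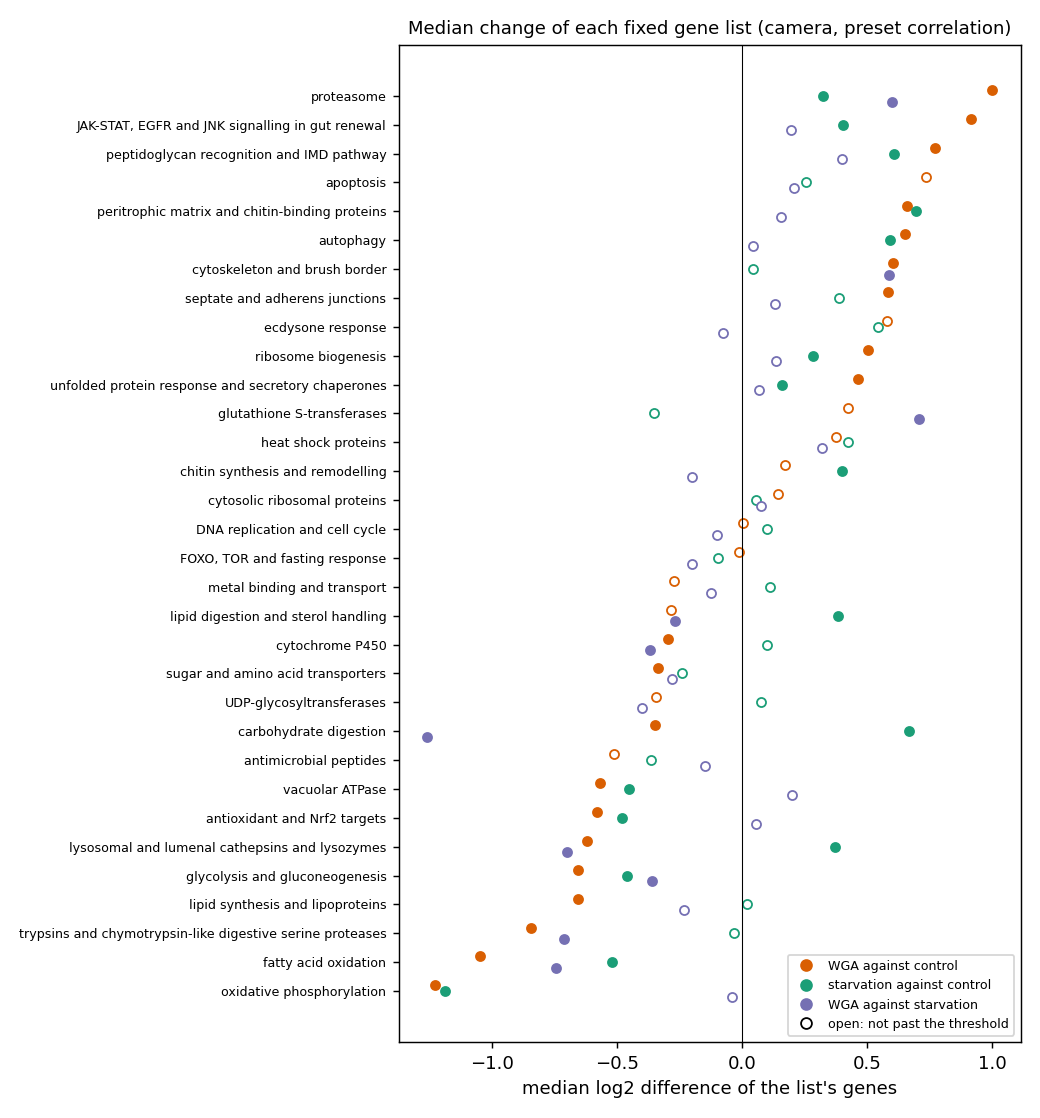
Median log2 difference (x axis) of the genes of each functional list in the 3 comparisons, with filled points where camera with a preset correlation passed the threshold and open points elsewhere, such as oxidative phosphorylation at -1.23, -1.19 and -0.04.

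Both treatments were compared with the same 3 control arrays to ask how far the responses overlap. Lip3, Cht4 and Amyrel rose in both, and AANATL6 and CG5892 fell in both. Together 480 probe sets rose in both comparisons and 439 fell in both, against 91.4 and 69.1 for independent lists and 0 in each of 100 simulations of unchanged groups that shared the controls. The simulated 0 reflects that unchanged groups give no shared calls, and it does not measure what the shared controls add. Opposite changes were seen for 38 probe sets, against 159 for independent lists. Across tested probe sets, which are not independent replicates, Pearson r of the log2 changes was 0.649, against a mean of 0.499 in the simulations. The covariance was 0.460, against 0.0857, and 73.5% of probe sets had the same sign, against 66.6%. The simulated r and share of the same sign come from groups without treatment effects. They are not the level for real but unrelated responses, so these gaps do not measure how far the responses agree. The controls could not be divided between the comparisons with at least 2 arrays each, so part of the excess over independent lists can come from sharing them. A difference in age from the controls, or a batch shared with them, could add to it and was not tested. Of the probe sets changed by WGA and not by starvation, 1143 in number, 537 also differed between WGA and starvation in the same direction. Of 515 changed by starvation and not by WGA, 183 differed directly in the corresponding direction.

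Genes changed in opposite directions included CG33116 2.14 ± 0.24 after WGA and -1.18 ± 0.24 after starvation, and CG33090 1.22 ± 0.19 after WGA and -1.12 ± 0.19 after starvation. CG32444 -1.25 ± 0.28, Phae2 -1.14 ± 0.17 and CG11162 -2.15 ± 0.25 fell after WGA and rose after starvation, by 1.62 ± 0.28, 1.41 ± 0.17 and 1.06 ± 0.25. The count of 38 was 19 without control replicate 2 and 24 without WGA replicate 2.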

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

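The tests of brightness, of ribosomal proteins, of the share of enterocytes and of the actin probe sets were chosen after the result was seen, as were scaling on spike-ins and the lists of the tricarboxylic acid cycle and mitochondrial ribosomal proteins. Control probe sets for fly genes, which the comparisons do not use, were brighter or dimmer after quantile normalisation on every array of a treatment than on every control array in these cases. After WGA the actin probe sets for the 3 prime end, 5 prime end and middle differed from control by 2.04, 2.46 and 2.39 on the log2 scale. The eIF-4a probe sets for these parts differed by 0.58, 1.02 and 0.88, and the 5 prime and middle probe sets of GAPDH by 0.42 and 0.31. After starvation the 5 prime and middle probe sets of eIF-4a differed by 0.93 and 0.74, and all 3 GAPDH probe sets were dimmer, with differences of -0.97, -1.17 and -1.15 at the 3 prime end, 5 prime end and middle. In the deposited signals the arrays overlapped for the 3 prime eIF-4a and middle GAPDH probe sets after WGA and the middle eIF-4a probe set after starvation.

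The actin signal was several-fold higher after WGA. Against RNA integrity or 3 prime bias as the whole cause, the changes of the 3 actin probe sets lay within 0.42 of each other. A change in actin transcripts, next to the rise of 12 of 23 cytoskeleton genes (adjusted p = 0.0989 for the list with an estimated correlation), is a candidate explanation and stays a hypothesis, because which actin genes the control probe sets detect was not tested.

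Oxidative phosphorylation genes had medians of -1.23 after WGA and -1.19 after starvation, and the list missed the threshold with an estimated correlation (adjusted p = 0.103 and 0.159). Against a bias with brightness, 0 of 10000 lists matched for signal had a median as low, the lowest being -0.71 and -0.52. Against a loss of short abundant transcripts, the ribosomal proteins had medians of 0.14 and 0.05 (0.054 in the lower case), and against scaling, the medians with spike-ins were -0.91 and -0.94 (-0.908 in the higher case). A wider fall of mitochondrial gene expression may be involved. Tricarboxylic acid cycle genes (8 of 9 and 7 of 9 fell) and mitochondrial ribosomal proteins (8 of 66 and 21 of 66 fell) had medians of -0.47 or lower (-0.466 the highest). With an estimated correlation, however, adjusted p = 0.154 and 0.302 for the cycle and 0.405 and 0.302 for the mitochondrial ribosomal proteins. Of all 9675 tested probe sets 975 fell after WGA and 686 after starvation, so the 8 of 66 after WGA was near the common share. RNA integrity stays open, since the 3 prime to 5 prime ratios disagree (eIF-4a highest in control, GAPDH highest after starvation, actin overlapping). A batch shared with the controls, which the labels do not rule out, stays open and untested. So do a difference in age from the controls and a response to lack of nutrients.

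Of 85 digestive genes, 40 were lower and 2 higher after WGA than after starvation, with a median of -0.78. The GAPDH 3 prime to 5 prime ratio also separated these groups, at 2.22 to 2.41 after WGA and 2.92 to 3.35 after starvation. The eIF-4a and actin ratios overlapped, and RNA integrity was not tested as a cause of this difference. With an estimated correlation only the trypsins passed (adjusted p = 0.00793), and carbohydrate digestion, lipid digestion and the cathepsins and lysozymes did not (0.0707, 0.18 and 0.213). Against a lower share of all enterocytes as the whole cause, these genes did not move alike, as they would if made by enterocytes alone. Of the 64 members at least 2 log2 units above the filter level, 64.1% lay over 3 SE from their common median. Of these, 17 lay above it and 24 below (differences of -5.73 to 0.63). That enterocytes alone make these transcripts was not tested. Among the 24 such trypsin-like proteases, 7 lay over 3 SE above their own median and 9 below (-4.98 to 0.1). A loss of enterocytes in part of the gut stays open. The markers of other cell types went both ways and many are dim (median of their mean log2 signals 4.21), so they decide nothing here. Probe sets marked as sharing probes did not carry the difference, since the 80 of 85 members without such a suffix had a median of -0.752 (-1.087 to -0.471). With so few marked, that median could hardly differ from the median of all 85. Cross-hybridisation between gene copies through unmarked probe sets was not tested. With the deposited scaling, which shifted the median of all tested probe sets by 0.35, the median of lipid digestion was 0.036. That list stayed low relative to other genes (adjusted p = 3.88e-08 with the preset correlation, while the main analysis gave 0.18 with an estimated one). Under all alternatives, the deposited and spike-in scaling among them, the medians of the other lists stayed below 0. They ran from -1.008 to -0.601 for the trypsins, -1.472 to -0.986 for carbohydrate digestion and -1.106 to -0.426 for the cathepsins and lysozymes. For these other lists the values argue against the scaling as the cause of the difference. Whether the lipid digestion transcripts fell in absolute amount stays open, and amounts per midgut were not analysed here. No other biological explanation of the difference was tested, and feeding was not measured here.

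For each comparison, the 6 arrays can be split into groups of 3 in 10 ways, which are too few for a share under 0.05. Only 1 split, the real one, called as many probe sets in each comparison. Fitted to 6 arrays, the real splits called 2106 (WGA against control), 1122 (starvation against control) and 1174 (WGA against starvation) probe sets, and the highest of the other splits called 0 in each.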

How the results depend on the processing

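Scaling on spike-ins was chosen after the result was seen, and the other alternatives before. No call reversed under any alternative. Over all comparisons, 47 list results were past the threshold, where a list can count in more than 1 comparison. The medians of 7 of these changed sign with the deposited scaling and of 5 with spike-in scaling, 5 and 4 of which still passed. These scalings also shifted the median of all tested probe sets, but not every list by the same amount. Of 373 named gene results, 368 kept their call with cyclic loess, 312 with the deposited scaling, 314 with spike-in scaling, 340 with median centring, 347 without a filter and 308 with a variance prior without a trend, and all kept their direction. Of 120 list results, 112 kept their side of the threshold with the deposited scaling and with median centring, 116 with cyclic loess, 114 with spike-in scaling and 76 with an estimated correlation. With the deposited scaling, WGA against control gave 2118 higher and 460 lower, WGA against starvation 1009 and 180, and the shared falls numbered 247 and the opposite changes 14. Spike-in scaling gave 2263 higher and 417 lower for WGA against control, 1758 and 255 for starvation against control, 350 and 274 for WGA against starvation, and 1160 shared rises, 173 shared falls and 18 opposite changes. Without a trend in the variance prior there were 515 rises after starvation, 345 lower after WGA than after starvation, 316 shared rises and 9 opposite changes. A replicate block gave 58 opposite changes. For these settings the cause was not tested. A minimum log2 change of 1, which can only lower a count, left 745 rises after WGA, 506 rises and 449 falls after starvation, 361 higher and 341 lower in WGA against starvation, 262 shared rises, 273 shared falls and 6 opposite changes. It was not run for gene lists. An estimated correlation left 2, 0 and 1 lists past the threshold. The estimates were far above the preset 0.01 for some lists, such as oxidative phosphorylation at 0.359 and the proteasome at 0.494. For such lists the preset value understates how far members move together, so its p values are too small. Lists with estimates near 0 were lost too, such as the unfolded protein response at -0.02, and the cause of those losses was not tested. With fry 98 of 120 list results kept their side of the threshold, 6 calls were lost and 16 were gained.

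With 1 array left out, and so fewer samples, the counts ranged as follows. WGA against control gave 752 to 1155 higher and 758 to 1015 lower, starvation against control 507 to 804 and 508 to 700, and WGA against starvation 363 to 619 and 358 to 570. Shared rises were 334 to 499, shared falls 328 to 433, opposite changes 19 to 42 and r 0.61 to 0.68. Lists past the threshold numbered 18 to 23, 13 to 16 and 9 to 11 in these comparisons. Signals near the filter level of 5.18 limit what can be said of dim genes.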

Other observations

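The 10 lists described here were chosen after the results of these same arrays were seen, and their p values are adjusted over these 10 only. Neither their counts nor their p values are independent evidence of a change or its direction. ESCRT machinery genes, which sort membrane proteins and remodel membranes, rose after WGA in 15 of 17 cases (median 1.36, adjusted p = 0.0219 with an estimated correlation). ALiX 2.63 ± 0.15, CHMP2B 2.40 ± 0.22, shrb 2.35 ± 0.22 and Vps2 2.16 ± 0.17 rose (log2 change ± SE, n = 3). After starvation 4 of 17 rose (adjusted p = 0.302 with an estimated correlation), and 11 of 17 were higher after WGA than after starvation (adjusted p = 0.0301 with an estimated correlation). Chaperonin and prefoldin genes, which fold actin and tubulin, rose in 12 of 18 cases after WGA (adjusted p = 0.199 with an estimated correlation), fell in 3 of 18 after starvation (adjusted p = 0.577 with an estimated correlation) and were higher in 17 of 18 after WGA than after starvation (adjusted p = 0.0605 with an estimated correlation). After WGA the chaperonin gene CCT2 1.43 ± 0.24 rose, as did Tbca 2.54 ± 0.19, a tubulin-binding cofactor gene that belongs to neither family.

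Of alkaline phosphatases, 0 of 12 were higher and 7 lower (camera adjusted p = 8.37e-06, adjusted p = 0.0223 with an estimated correlation) in WGA against control. Against starvation, WGA gave a result in which 0 of 12 were higher and 5 lower (camera adjusted p = 0.000849, adjusted p = 0.0605 with an estimated correlation), and for starvation against control 0 of 12 were higher and 3 lower (camera adjusted p = 0.0467, adjusted p = 0.302 with an estimated correlation). Alp7 -4.50 ± 0.60 and Alp4 -4.16 ± 0.38 fell after WGA. Of arylalkylamine N-acetyltransferase-like genes, 0 of 6 were higher and 4 lower (camera adjusted p = 2.98e-05, adjusted p = 0.0219 with an estimated correlation) in WGA against control. Compared with starvation, 0 of 6 were higher and 4 lower (camera adjusted p = 0.00013, adjusted p = 0.0301 with an estimated correlation), and for starvation against control 0 of 6 were higher and 2 lower (camera adjusted p = 0.155). Of aminoacyl-tRNA synthetases, 8 of 28 were higher and 0 lower (camera adjusted p = 0.0039, adjusted p = 0.375 with an estimated correlation) in WGA against control. With WGA against starvation, 6 of 28 were higher and 0 lower (camera adjusted p = 0.000101, adjusted p = 0.315 with an estimated correlation), and for starvation against control 0 of 28 were higher and 1 lower (camera adjusted p = 0.725). Of Rab GTPases, 4 of 17 were higher and 0 lower (camera adjusted p = 0.136) in WGA against control. After WGA relative to starvation, 1 of 17 were higher and 0 lower (camera adjusted p = 0.281), and for starvation against control 2 of 17 were higher and 0 lower (camera adjusted p = 0.599). Of spliceosomal snRNP and SR proteins, 3 of 13 were higher and 0 lower (camera adjusted p = 0.305) in WGA against control. In the direct comparison of treatments, 1 of 13 were higher and 0 lower (camera adjusted p = 0.121), and for starvation against control 1 of 13 were higher and 0 lower (camera adjusted p = 0.725). Of tetraspanins, 7 of 29 were higher and 2 lower (camera adjusted p = 0.122) in WGA against control. Between the treatments, 7 of 29 were higher and 1 lower (camera adjusted p = 0.281), and for starvation against control 2 of 29 were higher and 2 lower (camera adjusted p = 0.155). For tetraspanins in WGA against starvation the median was -0.11, the mean -0.02 and the direction of the test up. In WGA against starvation, 1 of 9 were higher and 2 lower (camera adjusted p = 0.121) for the tricarboxylic acid cycle and 2 of 66 were higher and 0 lower (camera adjusted p = 0.000168, adjusted p = 0.471 with an estimated correlation) for mitochondrial ribosomal proteins. For Rab GTPases after starvation the median was -0.02, the mean 0.07 and the direction of the test up.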
